A study of Arabidopsis thaliana with 6 samples.

How the data were processed

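Small RNA sequencing was run on 6 libraries, 3 of Col-0 and 3 of ein2-1, from Arabidopsis thaliana leaf explants after 1 hour of submergence of the seedlings and 7 days on callus-inducing medium. Per the submitters' processing notes, adapters were removed with cutadapt and TAIR10 was the genome. The aligner, the counting tool and their versions are not given in the sources used here.

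The deposited tables give raw counts per miRNA precursor for each library. Entries with the same mature sequence carry identical counts, so that 178 entries hold 142 distinct sequences. The authors also give a normalised value, a score scaled to an effective library size, rounded to whole numbers. Per the file headers, the authors' comparison gives a log2 fold change of ein2-1 over Col-0, a mean log2 CPM, a likelihood ratio score and a p-value with its FDR, which was adjusted over 178 entries. The log2 fold changes differed by at most 0.0193 from an edgeR likelihood ratio test rerun on the 178 entries. The deposited target sheet gives the psRNATarget expectation, a score of each predicted site, for 23944 pairs of entry and site, none above 5. The counts of targets refer to the pairs used here.

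Each mature sequence was placed on the TAIR10.1 reference by exact match and named after the annotated mature product or MIR gene at its site. Sequences with no match on the same strand as an annotated MIR gene were called unannotated and numbered by their entry, so that a match antisense to a MIR gene counts as unannotated. Coordinates of 13694 of the 13696 target transcripts found in the reference lay within the reference gene. Target sites were placed on the genome by an unbroken exact match within the span of the gene. Exons and coding sequence then gave their place. A site with no such match was taken to span an exon junction.

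Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM scaling, filterByExpr with its defaults, two-sided, Benjamini-Hochberg adjusted p below 0.05), with genotype as the only term. Fold changes are ein2-1 over Col-0. The filter kept 153 entries, which hold 118 distinct sequences, and left out 25 entries with 0.0175% of the counts. On the level of entries, 57 rose and 54 fell. Adjustment was over entries, and counts in the text refer to distinct sequences unless entries are named. Replicate numbers were not taken as pairs, since nothing in the labels gives a shared day or batch. Total counts per library were 559411 to 1882664. The TMM factors were 1.20 to 1.32 in Col-0 and 0.737 to 0.853 in ein2-1. The table names no spiked-in RNA, so a shift of all miRNAs together was not measured.

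The test was checked on simulated data, with 20 simulations of 118 sequences of which 40 were changed. It recovered 78.3% of 2-fold and 99.7% of 4-fold changes, and 3.44% of its calls were false. The simulated data had no repeated entries and as many rises as falls. Fewer sequences were changed in them than were called here, so these rates may not carry over. The target test was checked on 20 simulations with a planted list of 30 genes, and found the planted list in 20, with 0 unchanged lists called. The fixed gene lists held 2 to 11 genes with a site, so this recovery need not apply to them.

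The 12 miRNA lists, 11 gene lists, tests, thresholds and the rule for naming miRNAs were chosen before the data were examined. The rule names the 12 largest rises and 12 largest falls with no overlap between the libraries of the genotypes, the 5 most abundant miRNAs, and of each list the most abundant member and the one with the smallest p. Other list members are given as examples of a list. Named targets are members of the fixed gene lists, or else the site with the best expectation. Lists were tested with fry and camera (limma 3.58.1, on voom values of the entries), adjusted over the 12 lists. A sequence carried by several entries thus counted once per entry in its list. For camera, a preset correlation of 0.01 and an estimated one were used. Gene lists were tested with Fisher's exact test (scipy 1.17.1) against the genes with a site for a tested sequence. Of 110 gene symbols, 107 were matched in the reference, and WIND2, WIND3 and WIND4 were not.

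Alternatives were RLE and library-size scaling, DESeq2 1.42.0, limma-voom, no filter, at least 10 counts in 3 libraries, a replicate block, other thresholds, 1 entry per distinct sequence, counts summed per family number, totals without the most abundant miRNA, and each library left out in turn. For targets they were a stricter expectation limit of 4, which kept 54.2% of pairs, a looser limit for changed miRNAs, and the authors' list. A further 3 scalings were chosen after seeing the data, namely RLE and library-size scaling with 1 entry per distinct sequence, and library-size scaling without miR166. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.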

Results

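Small RNAs were sequenced from Arabidopsis thaliana leaf explants of 2 genotypes, the wild type Col-0 and ein2-1. The ein2-1 line carries a mutation in EIN2, a membrane protein that passes the ethylene signal on to the nucleus, and is insensitive to ethylene. Seedlings 14 days old were submerged for 1 hour, and their leaf explants were then kept for 7 days on callus-inducing medium (CIM), on which cut tissue forms a mass of dividing cells. The upper part of the explants was collected. Each genotype had 3 libraries, stated to be biological replicates by the design text, with Col-0 as the control. The comparison asks which miRNAs differ in level when ethylene signalling through EIN2 is lost in explants that had been under water. All libraries had the same submergence and time on CIM, so an effect of either cannot be read from the comparison.

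EIN2 is a protein-coding gene, and a table of miRNAs holds no value for it, so the genotype of the libraries was not checked this way. The table held 178 precursor entries with 142 distinct mature sequences, since 23 sequences were carried by more than 1 entry. Of the distinct sequences, 75 lay at annotated MIR genes of the TAIR10.1 reference and 67 did not, of which 55 were 24 nt long. The total count over the 178 entries was 940058, 559411 and 569132 in Col-0 replicates 1 to 3 and 1163907, 1882664 and 1430472 in ein2-1 replicates 1 to 3. These totals cover the listed miRNA entries alone and are not the sequencing depth of the libraries. A sequence carried by several entries is counted once per entry in these totals and in the normalised counts (CPM) derived from them. With each distinct sequence counted once, the totals were 556692, 333025 and 337045 in Col-0 and 606476, 987089 and 739601 in ein2-1. Reads without molecular identifiers are not independent molecules. Rank correlations across sequences between replicates of one genotype were 0.946 to 0.967 (Spearman, sequences not being independent replicates), and replicates differed by more than counting noise in each of the 6 pairs.

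Loss of EIN2 went with changes in most of the measured miRNAs, in both directions. The 4 largest rises among annotated miRNAs were those of miR399, miR160, miR393 and miR398b/c, which act on phosphate uptake, auxin response factors, auxin receptors and copper proteins. The largest falls among annotated miRNAs were those of miR167c-3p, miR398a-5p, miR779.2, miR319c and miR8184. Among the most abundant miRNAs, miR166 rose and miR158a did not pass the threshold. Of 118 distinct sequences tested, 41 rose, 38 fell and 39 did not pass an adjusted p of 0.05 (edgeR). Fold changes in the text are from TMM scaling unless another scaling is named. Of the changed ones, 27 rises and 33 falls were at least 2-fold. The libraries of the genotypes did not overlap for 42 sequences that lay higher and 37 that lay lower in ein2-1, or 66.9% of those tested, where chance gives 10%.

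The balance of rises and falls depended on the scaling. Rises made up 51.9% of the changed sequences under TMM scaling, 49.4% under RLE, 26.3% under library-size scaling and 39.7% under TMM with 1 entry per distinct sequence. The median log2 fold change was 0.06 under TMM and -0.07, -0.64 and -0.17 under these scalings, and the median of the shifts of single sequences against TMM was -0.12, -0.69 and -0.20. Leaving miR166, the most abundant miRNA, out of the totals of library-size scaling gave 40.5% rises. Over 7 scalings, 3 of them chosen after seeing the data, 21 sequences rose in each and 37 fell in each, and 0 were called in opposite directions. Under TMM 22 annotated miRNAs rose and 30 fell, of which 13 rises and all 30 falls held under each of the 7 scalings. Each scaling other than TMM shifted values down, by a median of -0.10 to -0.69. Falls could thus hardly be lost, and only the rises were put to a test. TMM with totals without the most abundant miRNA, which turned miR400 from -0.17 to 0.10, is not among the 7. Under it, 0 of the 38 named miRNAs lost a call.

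**Figure D1:**
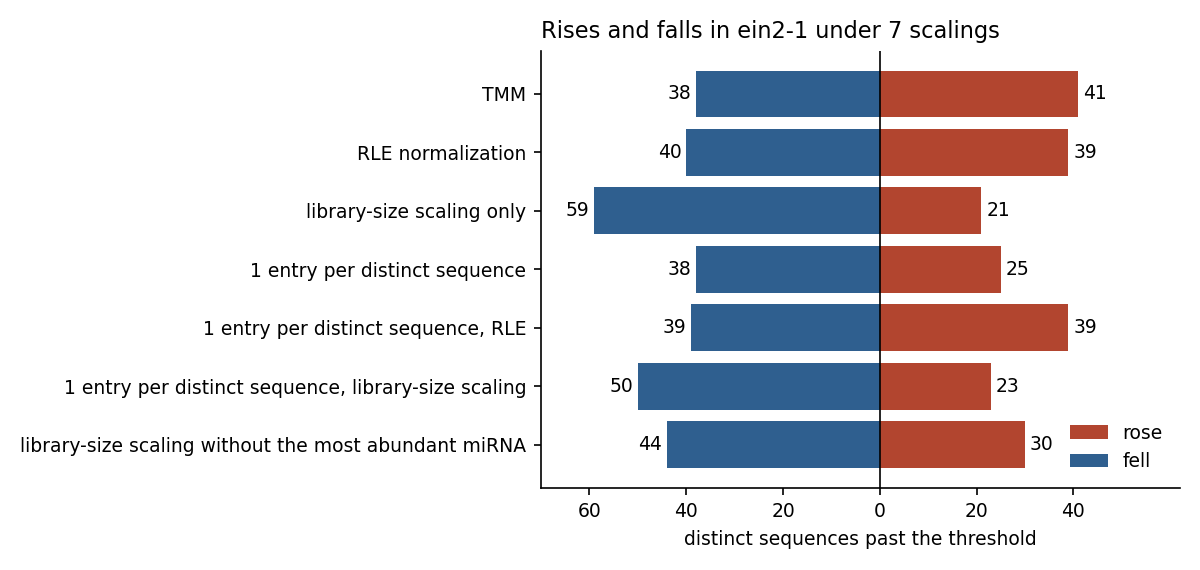
Number of distinct mature sequences past an adjusted p of 0.05 in ein2-1 against Col-0 (edgeR), with rises to the right and falls to the left, under each of 7 scalings. Falls outnumbered rises under library-size scaling (59 against 21), whereas TMM gave 41 rises and 38 falls.

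The 12 largest rises and the 12 largest falls kept their direction and passed the threshold under each of the 7 scalings. miR399b/c-3p, made in phosphate-starved shoots and directed against the phosphate regulator PHO2, rose by 3.49 on the log2 scale (SE 0.24, edgeR adjusted p 4.8e-08), from 42.4 ± 5.77 to 482.4 ± 62.4 CPM (counts scaled to the library total by TMM; SD, n = 3). miR160a/b/c-5p, which cuts the messages of repressing auxin response factors, rose by 3.05 (SE 0.17, edgeR adjusted p 1.2e-08), from 1870 ± 95.4 to 15441 ± 2444 CPM (SD, n = 3). miR393a/b-5p, directed against the TIR1/AFB auxin receptors, rose by 2.97 (SE 0.25, edgeR adjusted p 3.2e-07). miR398b/c-3p, a copper-responsive miRNA, rose by 2.68 (SE 0.24, edgeR adjusted p 4.2e-07). The other annotated miRNAs among the largest rises were miR5998a/b, miR843 and miR861-3p, at 2.37, 2.13 and 1.98. These started from low levels in Col-0, at 15.1 ± 3.55, 8.28 ± 6.63 and 14.2 ± 6.38 CPM (SD, n = 3). The remaining 5 were unannotated sequences, numbered here by their entry in the table. Unannotated 309 matched an intergenic stretch of the chloroplast genome at positions 11489 to 11510 and rose by 2.59. Unannotated 190, 61 and 102 rose by 2.22, 2.22 and 2.04, and unannotated 104 by an amount above each of these. The 5 unannotated sequences were also low in Col-0, with means of 3.43 to 13.6 CPM.

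miR167c-3p, the strand opposite the one that targets ARF6 and ARF8, had a log2 fold change of -4.09 (SE 0.28, edgeR adjusted p 4.8e-08), from 1570 ± 121 to 92.9 ± 35.1 CPM (SD, n = 3). miR398a-5p, from MIR398a on chromosome 2 (1040948 to 1040968), had -4.00 (SE 0.28, edgeR adjusted p 5.7e-08). Unannotated 196 lay antisense to MIR447a and MIR447b on chromosome 4 (from 1528335 and 1535626) and had -3.99. miR319c, a regulator of TCP genes of leaf growth, had -3.08 (SE 0.25, edgeR adjusted p 2.0e-07). The nutrient-responsive miR169h/i/j/k/l/m/n and a 19-nt product of MIR169i/j/k/m had -2.83 and -2.82. The others were miR779.2 at -3.23, miR8184 at -3.08, miR860 at -3.04, miR773a at -2.93, miR848 at -2.92 and miR5028 at -2.90.

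**Figure D2:**
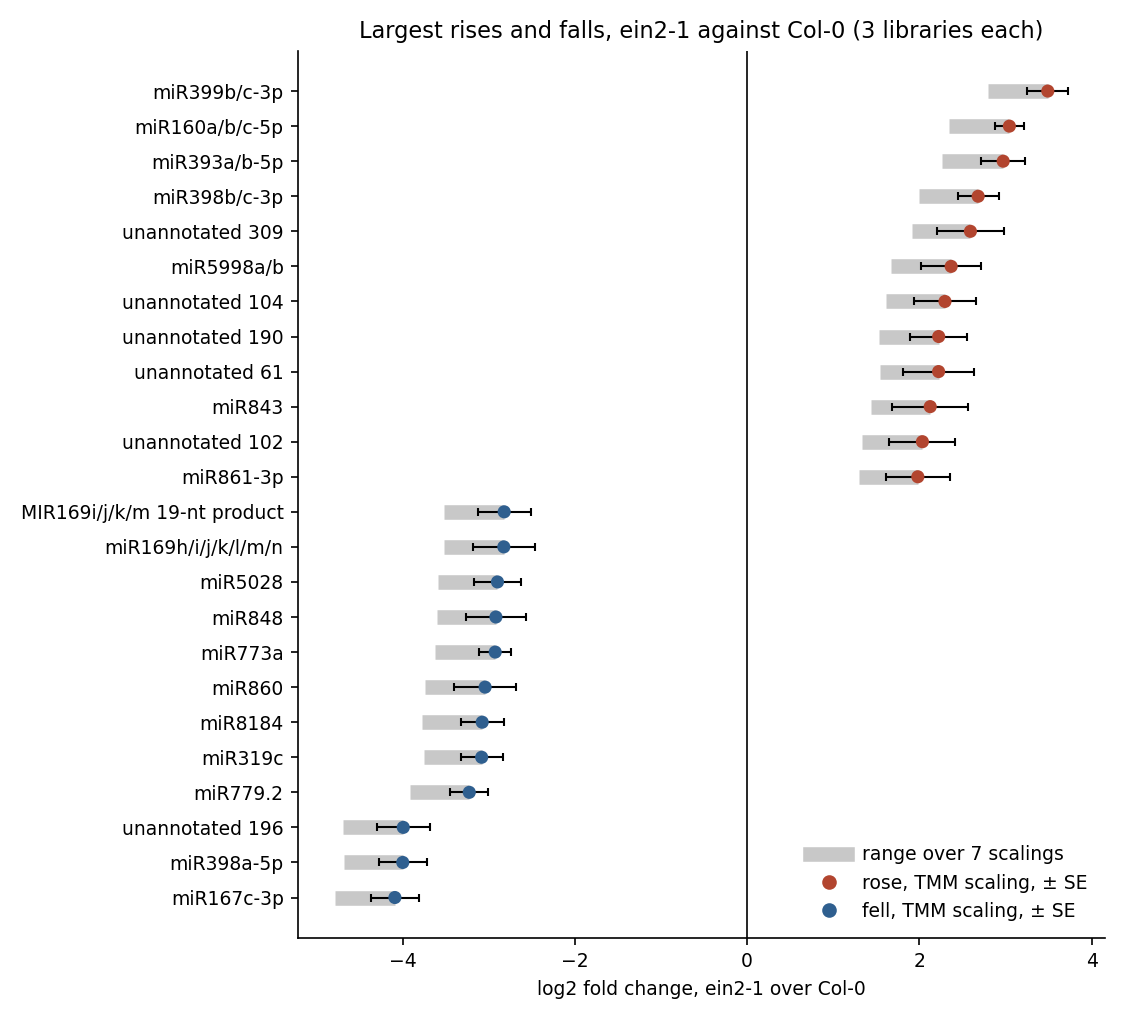
Log2 fold change (ein2-1 over Col-0, 3 libraries each) of the 12 largest rises and 12 largest falls, as points with the standard error under TMM scaling. Grey bars give the range over 7 scalings, and none of the 24 bars crosses 0, from miR399b/c-3p at 3.49 to miR167c-3p at -4.09.

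The most abundant miRNA, miR166a/b/c/d/e/f/g-3p, which limits the HD-ZIP III factors of meristems and upper leaf sides, rose by 1.08 (SE 0.13, edgeR adjusted p 5.2e-06) and rose under each of the 7 scalings. Its share of the distinct-sequence total was 25.0% to 26.0% in Col-0 and 37.2% to 38.7% in ein2-1. In the totals over the 178 entries it is counted 3 times. There its share was 44.60% to 46.19% in Col-0 and 58.20% to 60.03% in ein2-1. miR158a-3p had a log2 fold change of 0.11 (SE 0.12, edgeR adjusted p 0.419), and did not pass. It fell in 2 of the 7 scalings, with -0.58 under library-size scaling, and rose by 0.35 without Col-0 replicate 1, where it passed (edgeR adjusted p 0.0253). miR159a, miR159b-3p and miR165a/b-3p rose by 0.60, 0.71 and 0.74 under TMM and in 4 of the 7 scalings. Under library-size scaling these values were -0.11, 0.01 and 0.07 and did not pass.

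**Figure D3:**
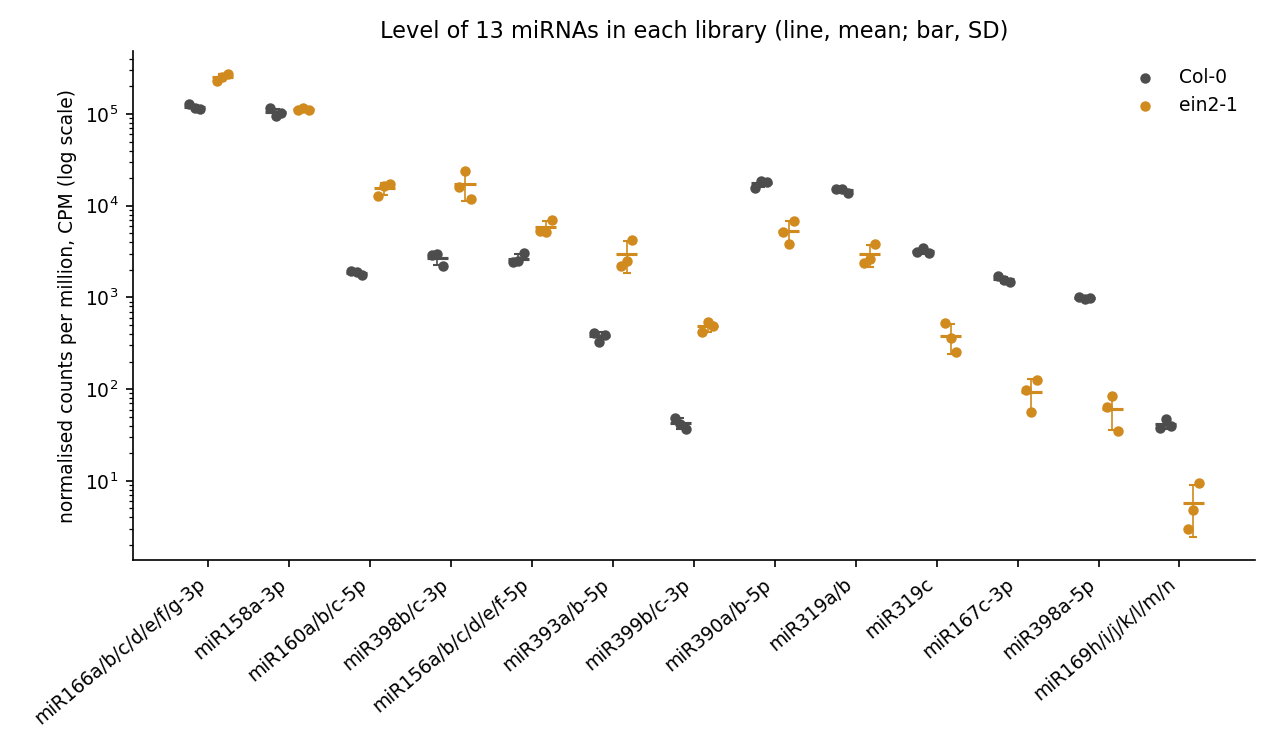
Normalised counts (CPM, log axis) of 13 named miRNAs in each of the 3 Col-0 and 3 ein2-1 libraries, with the mean as a line and the SD as a bar. The 3 ein2-1 libraries lie above the 3 Col-0 libraries for miR166, miR160, miR398b/c, miR156, miR393 and miR399 and below them for miR390, miR319, miR167c-3p, miR398a-5p and miR169. miR158a-3p overlaps, and its direction flips under library-size scaling.

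Auxin drives callus formation on CIM, and the auxin list changed in both directions. Of its 6 sequences tested, 3 rose and 3 fell. miR160 and miR393 rose under each scaling, whereas miR847 rose by 0.90 and passed under 1 of the 7. miR390a/b-5p, the trigger of the small RNAs that restrain ARF2, ARF3 and ARF4, had -1.74 (SE 0.20, edgeR adjusted p 4.9e-06), and miR167c-3p and miR167a-3p fell as well, each under all 7 scalings. Both miR167 sequences are 3p strands. The opposite strand, which targets ARF6 and ARF8, was not among the entries, so its level is not known here. The list as a set did not pass (fry adjusted p 0.129). Its median was -0.09 and its mean 0.00, with fry pointing up, and down under library-size scaling and with 1 entry per distinct sequence. It passed without any 1 of the 3 Col-0 libraries (fry adjusted p 0.0355, 0.0249 and 0.0187) and without ein2-1 replicate 3 (0.0060), and under RLE (0.0159). It did not pass with camera (adjusted p 0.910, and 0.947 with an estimated correlation), nor under RLE (0.832 and 0.837).

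miR156 and miR172 time the passage from juvenile to adult growth. Of 5 sequences in the timing list, 4 rose, of which 2 under each scaling, 0 fell and 1 did not pass. miR156a/b/c/d/e/f-5p rose by 1.13 (SE 0.18, edgeR adjusted p 6.3e-05) and miR172b/e-5p by 1.95, and both rose under each scaling. The more abundant miR172a/b-3p, the strand that targets AP2-like genes, rose by 0.71 but passed in 3 of the 7 scalings, and its value was -0.0005 under library-size scaling. miR157a/b/c-5p, at 0.35, did not pass, and turned to -0.36 under library-size scaling. It passed as a rise without any 1 of the 3 Col-0 libraries (0.42, 0.54 and 0.56) and without ein2-1 replicate 1 (0.45). The list passed with fry (adjusted p 0.0174) and with camera at a preset correlation (adjusted p 0.0112), but had an adjusted p of 0.662 with an estimated correlation. The fry value was 0.366 under library-size scaling. The list of low-oxygen-responsive miRNAs, fixed from earlier hypoxia profiling, shares its miR156, miR157 and miR172 members. It had 7 rises, 0 falls and 2 not passed among 9 sequences, but 3 of the rises held under each scaling, and miR159a turned to -0.11 under library-size scaling. The list had fry at 0.0122, camera at 0.0036 and camera at 0.608 with an estimated correlation (adjusted p). Under library-size scaling its fry adjusted p was 0.634. As all libraries came from submerged seedlings, these values compare genotypes and do not measure a response to low oxygen. miR391-3p rose by 1.57, and by 0.86 to 1.57 over the 7 scalings.

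The leaf form list, with the miRNAs of cell proliferation in leaves, changed in both directions. Of 6 sequences, 2 rose, 2 fell and 2 did not pass. Both miR319 sequences fell under each scaling, miR319a/b with -2.33 (SE 0.19, edgeR adjusted p 2.0e-07), while miR159a and miR159b-3p rose in 4 of the 7, miR159a turning to -0.11 under library-size scaling. miR396a-5p had -0.08 and did not pass, but fell in 3 of the 7 scalings, with -0.77 under library-size scaling. fry pointed down (adjusted p 0.0023), as did the mean of -0.62, whereas the median was 0.21. The list did not pass with camera (adjusted p 0.629, and 0.662 with an estimated correlation). The fry adjusted p was 0.0689 with 1 entry per distinct sequence. In the list that stands for remaining differentiated leaf tissue, miR319c and miR319a/b fell and miR408-3p rose by 0.53, which turned to -0.17 under library-size scaling. That list of 3 sequences passed with fry (adjusted p 0.0007) and not with camera (adjusted p 0.146, and 0.608 with an estimated correlation).

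The meristem and polarity list held 7 sequences, of which 3 rose, 2 fell and 2 did not pass. miR166 and miR171a-3p rose under each scaling, and miR394a/b-5p and miR171b-5p fell under each, with -1.43 and -2.38 under TMM. Its median was 0.35 and its mean over distinct sequences -0.05. fry pointed up (adjusted p 0.0368) and camera did not pass (adjusted p 0.487, and 0.662 with an estimated correlation). The fry call was lost with a replicate block (adjusted p 0.113), and with 1 entry per distinct sequence it pointed down and did not pass (adjusted p 0.474), and it also pointed down under library-size scaling (adjusted p 0.154). Without ein2-1 replicate 1 it had an adjusted p of 0.0824.

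Of the 4 sequences in the list of small-RNA machinery and its triggers, 3 fell, 0 rose and 1 did not pass, namely miR162a/b-3p at 0.38, which turned to -0.31 under library-size scaling. miR168a/b-5p, which targets the slicer AGO1, had -1.14, and miR161.2 had -0.90, and both fell under each scaling, as did miR390a/b-5p. The list passed with fry (adjusted p 0.0013) and not with camera (adjusted p 0.146, and 0.608 with an estimated correlation).

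Phosphate, nitrogen, sulfate and copper supply are each known to act on certain miRNAs. In the phosphate list miR399b/c-3p and miR827 rose, and the list of 2 passed with fry (adjusted p 0.0007), though miR827, at 0.62, passed in 3 of the 7 scalings and had -0.08 under library-size scaling. The phosphate list did not pass with camera (adjusted p 0.166, and 0.608 with an estimated correlation). In the sulfate and nitrogen list all tested members belonged to miR169, and 3 of 4 sequences fell and 0 rose. A product of the sulfate-responsive MIR395a/e did not pass the count filter, and the authors' table gives it a log2 fold change of 0.79 at an FDR of 0.115. The sulfate and nitrogen list passed with fry (adjusted p 0.0023) and with camera at a preset correlation (adjusted p 0.0004), but had an adjusted p of 0.608 with an estimated correlation. The copper list held 4 sequences, of which 2 rose, 1 fell and 1 did not pass, and fry gave an adjusted p of 0.0617. Its median was 0.30 and its mean -0.18, while fry pointed up, and down under library-size scaling and with 1 entry per distinct sequence. It passed with a replicate block (fry adjusted p 0.0191) and not with camera (adjusted p 0.487, and 0.662 with an estimated correlation).

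In the immune and stress list miR842 fell with -1.99 (SE 0.36, edgeR adjusted p 0.0002) and fell under each scaling. miR400, at -0.17, did not pass, but fell in 2 of the 7 scalings, with -0.88 under library-size scaling. Its fry adjusted p of 0.0402 went to 0.0820 and 0.0677 without Col-0 replicate 1 or 2, and to 0.115 and 0.0935 without ein2-1 replicate 1 or 2. It was 0.125 with a replicate block, and camera did not pass (adjusted p 0.522, and 0.662 with an estimated correlation). The ethylene and senescence list was miR164a/b-5p alone, at 0.49 (SE 0.25, edgeR adjusted p 0.0889), which did not pass and had -0.20 under library-size scaling. It passed as a rise without Col-0 replicate 2 or 3 (0.72 and 0.71). fry gave an adjusted p of 0.0223 for its 2 identical entries and 0.474 with 1 entry, and 0.0724 and 0.0513 without ein2-1 replicate 1 or 3. It was 0.0855 under RLE and 0.0737 with a replicate block, and camera gave 0.522 (0.662 with an estimated correlation). fry asks whether the members of a list move, on balance, one way, and compares them with no other miRNA, while camera compares a list with the other miRNAs. Across the 12 lists, fry passed 10, camera 3 with a preset correlation and 0 with an estimated correlation. Both tests ran on entries, so repeated entries of a sequence counted as separate members. The 3 that camera passed, timing, low oxygen, and sulfate and nitrogen, held 11, 15 and 12 entries for 5, 9 and 4 sequences. Their estimated correlations were 0.84, 0.54 and 0.66, above the preset 0.01. Adjusted over the list alone, the calls in the lists were those given above, with 1 further rise in the small-RNA machinery list.

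The authors' own list held 46 entries with 29 distinct sequences, 23 entries up and 23 down. All 46 were called here. Of the 122 entries at the authors' FDR below 0.05, 120 were tested here and 108 were called, each in the authors' direction. The authors named 17 of the entries they listed Unknown, and 10 of the 12 distinct sequences behind these matched an annotated MIR gene.

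The target sheet lists genes with predicted sites for each miRNA. These are sequence predictions, and levels of the target messages were not measured here. miR399b/c-3p had its best site in the 5′ UTR of PHO2 (AT2G33770, chromosome 2, 14281884 to 14281904, expectation 1.5, lower being a better match). miR160a/b/c-5p had sites in the coding sequences of ARF17 (AT1G77850, chromosome 1, 29274189 to 29274209), ARF10 and ARF16, with expectations of 0.5, 1.0 and 1.5. miR393a/b-5p had sites in the coding sequences of TIR1 (AT3G62980, chromosome 3, 23273727 to 23273748), AFB2 and AFB3, each at 1.0, and in AFB1, listed as GRH1, at 2.0. Among genes of ethylene signalling, miR398b/c-3p had a site in the coding sequence of the ethylene repressor CTR1 (AT5G03730, chromosome 5, 979224 to 979244) at an expectation of 4.0. Unannotated 104, a 24-nt sequence with 17 exact genome sites, had its best site in ACS7 (AT4G26200), an ethylene synthesis gene, at 2.0. That site had no unbroken match in the gene and was taken to span an exon junction. Unannotated 309, the chloroplast sequence, had a site in the low-oxygen factor RAP2.3, listed as EBP (AT3G16770), at 4.0. Its mean level was low, at 3.43 CPM in Col-0 and 21.7 CPM in ein2-1. Whether either sequence acts as a miRNA was not tested. miR861-3p had one in the wound regulator WIND1, listed as RAP2.4 (AT1G78080), at 4.0. miR843 had sites in TCP4 at 2.5 and ARF4 at 4.0.

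Among the fallen miRNAs, miR319c had sites in the coding sequences of TCP24, TCP10, TCP4 and TCP2, each at 3.5, and TCP3 at 4.5. miR169h/i/j/k/l/m/n had its best site in the 3′ UTR of NF-YA5 (AT1G54160, chromosome 1, 20217494 to 20217514) at 1.0. miR860 had its best-scoring site in the 3′ UTR of the ferrochelatase gene FC1 (AT5G26030, chromosome 5, 9098811 to 9098831) at 0.5. MIR860 itself holds the miRNA close by on the same strand, at 9098876 to 9098896. Pairing within the MIR860 precursor therefore cannot be told apart from a target site in FC1. The best sites of miR848, miR5028 and miR167c-3p were in MYB118, DI19 and NRPB2, each at 2.5. Those of miR8184, miR398a-5p and miR773a were in AT4G18660 at 2.0, AT5G06120 at 2.0 and AT1G35660 at 1.5.

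The tested sequences had predicted sites in 6852 genes, with a median of 72 genes per sequence, and the changed ones in 4900 of these. Risen sequences had sites in 2608 genes and fallen ones in 2660, with 368 in both. Of 11 fixed gene lists, 2 differed from this background (Fisher's exact test, two-sided, adjusted over the lists). Since 71.5% of the background genes were targets of a changed sequence, lists this small could hardly pass by holding more targets. The test could thus mainly call lists with few targets, and each of the 2 called rests on 1 miRNA. None of the 7 GRF genes was a target of a changed miRNA (adjusted p 0.0017), as each rests on miR396a-5p. That miRNA fell in 3 of the 7 scalings, under which all 7 would be targets of a changed miRNA. None of the 4 NAC genes of miR164 was either (adjusted p 0.0361), which is no longer so at an adjusted p limit of 0.1 for the miRNAs. All 11 SPL genes were targets (adjusted p 0.150), as were 9 of 10 auxin response genes (adjusted p 0.442), 6 of 6 AP2-like genes and 5 of 5 in both the HD-ZIP III and TCP lists. The ethylene signalling list had 3 of 3, low oxygen 3 of 6, callus and regeneration 1 of 3, and leaf photosynthesis markers 2 of 2. With the 29 sequences of the authors' list as the changed ones, the SPL, auxin, HD-ZIP III and TCP lists passed (adjusted p 2.9e-05, 0.0363, 0.0107 and 0.0107) and the GRF list did not (adjusted p 0.235). Genes that share a miRNA are not independent, so these tests count genes rather than separate events.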

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

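The scalings with 1 entry per distinct sequence by RLE or by library size, and library-size scaling without miR166, were chosen after seeing the data. Of 38 named miRNAs, 28 kept their direction and stayed past the threshold under every alternative run on them. The cause was not tested for the changes below unless stated. How far depth limits the calls was not tested, as no alternative varied it.

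Rising entries, 57, numbered 32 under library-size scaling, 25 with 1 entry per distinct sequence and 23 with library-size scaling of these. Rising distinct sequences, 41, numbered 21, 25 and 23 in the same settings, 27 when at least 2-fold was also asked and 22 with counts summed per family. With 1 entry per distinct sequence the TMM factors ran from 0.666 to 1.15 within ein2-1, and RLE on the same entries gave 39 rising sequences. Falling distinct sequences, 38, numbered 59 under library-size scaling. Without each library in turn, 52 to 67 entries rose and 50 to 53 fell, and 36 to 49 distinct sequences rose and 34 to 37 fell.

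Under library-size scaling the log2 fold change turned to -0.58 for miR158a-3p, -0.11 for miR159a, -0.36 for miR157a/b/c-5p, -0.082 for miR827 and -0.20 for miR164a/b-5p. With 1 entry per distinct sequence and library-size scaling it was -0.39, -0.17 and -0.011 for miR158a-3p, miR157a/b/c-5p and miR164a/b-5p. miR158a-3p also had -0.0169 with DESeq2, -0.010 with 1 entry per distinct sequence and -0.15 with library-size scaling without miR166. miR400 turned to 0.10 with library totals without the most abundant miRNA and to 0.048 without Col-0 replicate 2, and ranged from -0.42 to 0.048 without each library in turn. Counts summed per family gave 1.83 for miR398a-5p, since that sum is mostly miR398b/c-3p, -0.33 for miR158a-3p and -0.13 for miR157a/b/c-5p, ended the call of miR171b-5p (-0.35, edgeR adjusted p 0.156) and left -1.65 of the -4.09 of miR167c-3p, which is summed there with miR167a-3p.

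Of the 12 miRNA lists, fry passed 10, camera 3 with a preset and 0 with an estimated correlation, and fry 6 under library-size scaling and 7 to 11 without each library in turn. Under library-size scaling fry turned down for auxin (adjusted p 0.180), meristem and polarity (0.154), copper (0.180) and ethylene and senescence (0.358), and with 1 entry per distinct sequence for auxin (0.671), meristem and polarity (0.474) and copper (0.474). The small-RNA machinery, phosphate, sulfate and nitrogen, and leaf tissue lists passed under all 10 alternatives of fry. Predicted targets numbered 4900 genes, against 2781 with the stricter expectation limit and 2135 from the authors' list, both of which use fewer pairs. Gene lists past the threshold numbered 1 at an adjusted p below 0.1 and 4 with the authors' list. There the side of the background changed for callus (adjusted p 1.00) and NAC genes of miR164 (0.795) at the looser limit, and for AP2-like genes (0.342) and leaf photosynthesis markers (1.00) with the authors' list.

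With the replicate number as a block, 58 entries rose and 52 fell, and fry passed 8 lists, losing meristem and polarity (0.113), immune (0.125) and ethylene and senescence (0.0737) and gaining copper (0.0191). Libraries of the same number had correlations of 0.208, -0.05 and 0.183 after removal of the genotype means. Numbers 1 and 3 were thus closest to their own number, as other pairs had at most 0.058, whereas Col-0 replicate 2 was closer to another number. The numbers were not taken as pairs because the labels give no shared day or batch, and these correlations do not settle whether they share one.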

Other observations

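The tests of the miRNA families, the 24-nt class and the share of rises were chosen after the result was seen, and what the count over other splits of the libraries would show was also written down after its result.

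Outside the fixed lists, falls outnumbered rises among annotated miRNAs in ein2-1. Of 31 annotated sequences in no list, 5 rose, 16 fell and 10 did not pass, and 4 rises and 16 falls held under each of the 7 scalings. The scalings other than TMM shifted values down, so the falls could hardly be lost under them. Besides those named by rule, examples chosen after their values were seen are miR781a/b at -1.46, miR839-5p at -1.45, miR4228-3p at -1.45, miR5640 at -1.34, miR840-5p at -1.28 and miR5026 at -1.05. miR841a/b-3p rose by 0.87 to 1.58 over the 7 scalings.

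Within the miR398 and miR171 families some products rose and others fell, and scaling alone cannot make a gap within a library. The log2 fold change of miR398b/c-3p exceeded that of miR398a-5p by 6.68, and that of miR171a-3p exceeded that of miR171b-5p by 3.98. Each pair sets a 3p arm against a 5p arm of another locus, and the other miR171 products, miR171b/c-3p at -0.29 and miR170-5p with miR171a-5p at 0.35, did not pass. The lowest count of the fallen sequences in an ein2-1 library was 29. This argues against a sequence variant of the ein2-1 line within them only if reads were counted as exact matches. The counting tool is not given, so the counts alone cannot decide this. A variant elsewhere in the precursor, processing of the arms, genotype and a different mix of tissues stay open and were not tested.

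The 24-nt unannotated sequences were tested as a class, since a rise of all of them might mark a change in another small-RNA pathway. Under TMM, 14 of these 36 sequences rose and 5 fell, against 22 rises and 30 falls among 72 annotated ones. Among all 46 unannotated sequences 19 rose and 8 fell under TMM, and 8 rises and 7 falls held under each of the 7 scalings. The median log2 fold change of the 24-nt sequences exceeded that of annotated miRNAs by 0.16 (bootstrap 95% interval -0.37 to 1.29, permutation test p 0.555, two-sided, 36 against 72 sequences). That interval is too wide to tell a class-wide rise from none. Both the interval and the test took sequences as the units, so they leave out variation between libraries. The 24-nt unannotated sequences held 0.217% ± 0.0155 of the distinct counts in Col-0 and 0.240% ± 0.0227 in ein2-1 (SD, n = 3).

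The share of rises depended on the scaling, with a range of 25.6 percentage points over TMM, RLE and library size. Repeated entries of a sequence are argued against as the whole cause in these libraries, as the range was still 18.5 points (bootstrap 95% interval 12.1 to 25.9) with 1 entry per distinct sequence. The intervals for the share resampled sequences with their calls held fixed, so they leave out variation between libraries. Counts taken by miR166 may explain part of it, since leaving miR166 out of the totals moved the share by 14.3 points (8.57 to 20.8). As miR166 rose, that step was bound to raise the other fold changes. It also dropped the 3 entries of miR166 together, so its abundance and its repeated entries cannot be told apart. A global shift of miRNA levels stays open and was not tested.

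Between ein2-1 and Col-0, 111 entries passed the threshold, and the highest of the other splits of the 6 libraries gave 0. Of the 10 splits, 1 gave as many, the real one, and 10 splits are too few for a share under 0.05.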
